A study of Homo sapiens with 8 samples.

How the data were processed

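The samples were MCF-7 cells grown in medium with 10% fetal bovine serum, from which total RNA was taken after 24 h of field or sham exposure and hybridised as biotin-labelled cRNA, per the labels' protocols. The deposited values are probe set intensities, the MAS5 signal on a linear scale, and MAS5 is named without a version in the submitters' processing notes. MAS5 summarises each probe set on its own array, subtracts mismatch signal and scales each array by a single factor, so weak signals are noisy and the shape of the signal distribution is not made equal between arrays. The scaling target and any pooling of cultures are not given in the sources used here. After leaving out 2% of probe sets at each end, the mean deposited intensity was 499.9 on each array of the 2.0 W/kg experiment and 133.1 to 140.4 on those of the 3.5 W/kg experiment, so the experiments were scaled differently. No pair of arrays held identical values for any probe set.

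Groups were taken from the sample labels, with 4 groups of 2 arrays: sham and exposed at 2.0 W/kg, and sham and exposed at 3.5 W/kg. The labels call the arrays biological replicates without saying whether they came from separate exposures. If they did not, the p-values measure only the spread between these arrays. Residual spread was estimated from all 8 arrays in a single fit with 4 residual degrees of freedom, so an array that stands apart widened the error of every group.

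Of 22283 deposited probe sets, 68 controls were left out, and the 50% of the remaining 22215 with the highest mean over all arrays were tested (11108). Signals were taken as log2(intensity + 16), so changes of weak signals are understated. Each probe set was tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05, for 5 contrasts: exposed minus sham at each level, the mean of both, the difference between levels, and the difference between the sham groups. A count with no test gave the probe sets that differed at least 2-fold in all pairs of an exposed and a sham array.

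Gene names came from the platform annotation, updated by gene identifier to the symbols of the GRCh38.p14 RefSeq table, which was used for names only. A single symbol was assigned to 19065 probe sets (19053 matched by identifier), several to 1043 and none to 2107, and a probe set with several was not named. The 9903 tested probe sets with a single symbol stood for 6850 genes, and for gene lists, markers and the contrasts other than the 2 single levels each gene was represented by its probe set with the highest mean. The 24 lists held 831 entries after symbols were updated. They were tested against all other genes with limma's camera at a preset correlation of 0.01, with camera's estimated correlation as an alternative, and adjusted over the 24 lists within each contrast. As a further alternative, fry tested whether the genes of a list shifted in a common direction, without reference to other genes. The smallest lists had few tested members, and some genes, such as BAX and KRT19, belong to more than 1 list.

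The named genes followed a fixed rule. For each level they were the 10 highest and 10 lowest differences among probe sets with a single symbol for which both exposed arrays lay on the same side of both sham arrays and the unadjusted p was under 0.05. In addition, the highest and lowest member of each list, 16 marker genes and, for the other contrasts, the 5 genes with the lowest p were named. The groups, tests, lists, named genes and most alternatives were fixed before the data were examined.

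The alternatives were a pseudocount of 1 or 64, all probe sets or the upper 25%, quantile normalization, a common 75th percentile for all arrays (290.4), eBayes without a trend, the replicate number as a block, only the 4 arrays of a level, a fold of 1.5 in the count of pairs, the mean over a gene's probe sets in the list tests, and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Array weights, a common scale combined with leaving out sham replicate 2 of 2.0 W/kg, the per-list and per-marker values without that array, the other probe sets of named genes and their values without single arrays, the lowest p over any probe set and the comparison of the experiments on a common scale were added after the data had been seen.

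The procedure was tested on simulated data for the 11108 probe sets, 200 of them changed, in 5 simulations for each level. Both groups of a level took its sham means, and the spread was the variance from the limma fit. The simulated data thus followed the model under test. At 2.0 W/kg it recovered 66.6% of 2-fold and 97.0% of 4-fold changes, with 5.43% false calls, and at 3.5 W/kg it recovered 67.2% and 97.2%, with 5.95% false calls. The 2.0 W/kg list test at the preset correlation was run in 20 simulations on 6850 uncorrelated genes. A list shifted by 0.3 on the log2 scale was found 20 times, and 0 of 400 lists sharing no gene with it were called. The estimated correlation and fry were not simulated. These simulations gave every array the same spread, which the real arrays did not have. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.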

Results

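MCF-7 cells, an established human breast cancer line that expresses the oestrogen receptor, were exposed for 24 h to an 1800 MHz radiofrequency field of the kind used by mobile telephones, or were sham-exposed in parallel. The field was switched on for 5 min and off for 10 min in turn. The experiment was run at 2 specific absorption rates, 2.0 W/kg and 3.5 W/kg, each with its own sham group. Transcript levels were read on Affymetrix arrays with 22283 probe sets, 2 arrays per group and 8 in all, and the labels call the arrays of a group biological replicates. The mean signal lay between 685.9 and 743.3 on the 4 arrays of the 2.0 W/kg experiment and between 198.7 and 201.9 on the 4 arrays of the 3.5 W/kg experiment, so the experiments were on different scales and each exposed group was set against its own sham group. The number of arrays limited the precision: the median 95% confidence interval of a within-level difference reached 0.47 on the log2 scale to either side. Differences are given as log2(signal + 16), exposed minus sham, with the standard error of the limma fit.

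The arrays themselves were not equally alike. Sham replicate 2 of the 2.0 W/kg experiment correlated with the other 7 arrays at r of 0.914 to 0.931 across the tested probe sets, which are not independent replicates, whereas the other arrays correlated among themselves at 0.972 to 0.986. Its median signal was 38.03% of its 75th percentile, against 24.2% to 27.7% on the others, so its weak signals were higher relative to its strong ones. Its signal for the spiked bacterial control BioB was 87.3, against 225.4 on the other sham array and 258.0 and 275.6 on the exposed arrays of that experiment. The spike CreX lay closer, at 9562 against 10558 on the other sham array and 11488 and 14080 on the exposed arrays. BioB also ranged from 21.3 to 52.2 among the 3.5 W/kg arrays. Several values at 2.0 W/kg are therefore also given without it, while single members of lists are given only with it.

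**Figure D1:**
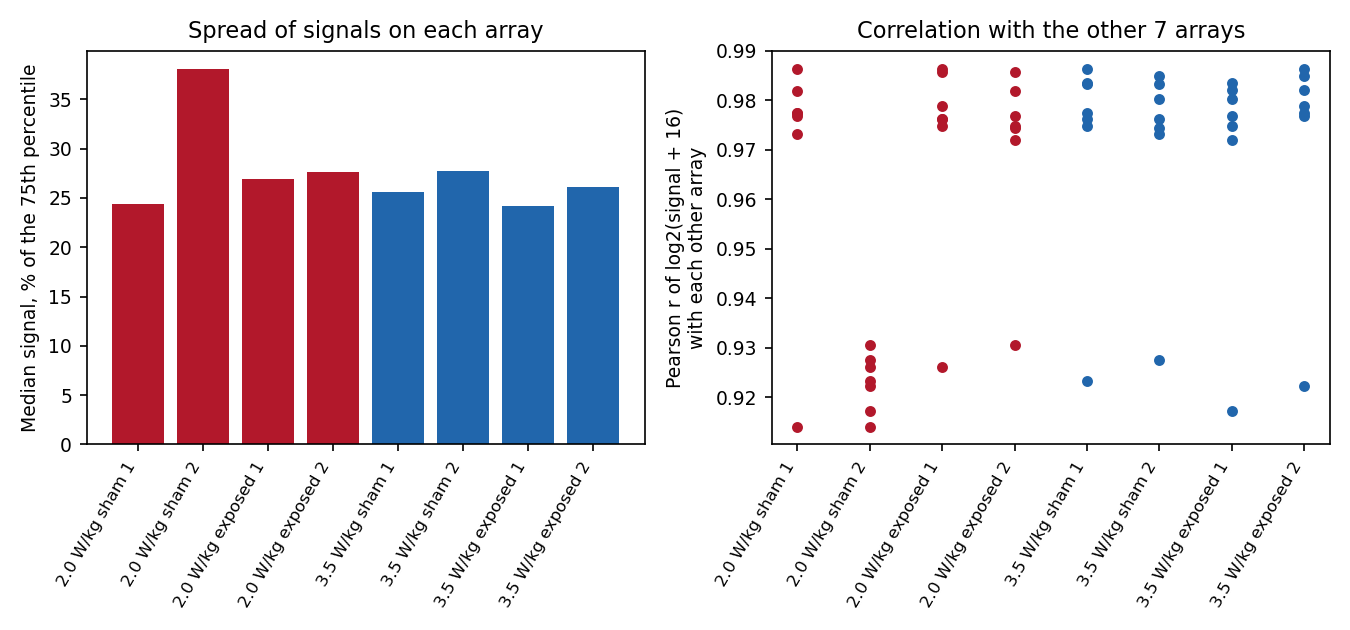
Left, the median signal of each array as a percentage of its 75th percentile (bars, 1 per array). Right, Pearson r of log2(signal + 16) with each of the other 7 arrays (points), with 2.0 W/kg arrays in red and 3.5 W/kg arrays in blue. Sham replicate 2 at 2.0 W/kg stands at 38.03% on the left and has no correlation above 0.931 on the right.

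The first comparison asked which transcripts differed after exposure at 2.0 W/kg. Genes were named from probe sets with a single symbol, no overlap between exposed and sham arrays and an unadjusted p under 0.05. Among these the highest differences belonged to PSMB2, a proteasome subunit, at 1.67 ± 0.58 (SE), PIP5K1A, a phosphoinositide kinase, at 1.60 ± 0.43, GGA1, an adaptor of Golgi transport, at 1.52 ± 0.64, SLC30A1, a zinc exporter, at 1.48 ± 0.51, and CD82, a tetraspanin known as a metastasis suppressor, at 1.40 ± 0.35. PPM1F (1.26), the elongin subunit ELOA (1.21), CA8 (1.17), DCUN1D4 (1.17) and ACACA (1.14), which encodes the enzyme that commits acetyl-CoA to fatty acid synthesis, followed. The lowest were RARA, a retinoic acid receptor, at -1.997 ± 0.49, WDTC1 at -1.62 ± 0.51, GCAT, an enzyme of threonine and glycine metabolism, at -1.43 ± 0.44, SQSTM1, an autophagy receptor, at -1.40 ± 0.47, and IRGQ at -1.37 ± 0.54. REM1 (-1.33), the interferon-inducible IFI27 (-1.29), JPT2 (-1.28), the carbonic anhydrase CA1 (-1.27) and the interferon-inducible OASL (-1.20) completed the lowest 10. Without that rule, a probe set with no single symbol stood higher (2.23 ± 0.99, SE). Each value comes from 1 probe set, and 13 of these 20 genes had another tested probe set. In 11 of the 13 no other probe set reached 50% of the named difference in its direction, a limit chosen after the values were seen. The strongest other probe set stood at 0.13 for PSMB2, 0.12 for GGA1, -0.14 for PIP5K1A, -0.08 for RARA, 0.08 for GCAT and -0.05 for SQSTM1, each with more signal than the named one. Only ACACA (0.82) and a second further probe set of PIP5K1A (1.34) reached it. CD82 and IFI27 had no other.

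None of these 20 differences passed the test over all genes. With limma, 0 of 11108 probe sets reached an adjusted p under 0.05 at 2.0 W/kg, the smallest adjusted p was 0.891, and 379 (3.41%) had an unadjusted p under 0.05 where chance gives about 555. Both exposed arrays lay above both sham arrays for 1557 probe sets and below them for 1577, together 28.2% of those tested, against 33.3% expected by chance. The 95% interval excluded a 2-fold change in either direction for 9305 probe sets (83.8%). Of the 20 values, 14 fell by over 1.5 times without the sham replicate that stood apart: GGA1 came to 0.20, ELOA to 0.21, PSMB2 to 0.55, SLC30A1 to 0.43, REM1 to -0.32 and OASL to -0.44, while CD82 stood at 1.65, RARA at -1.34 and IFI27 at -1.17. Other arrays mattered too: without exposed replicate 1, IRGQ came to -0.27, JPT2 to -0.60, WDTC1 to -0.92 and RARA to -1.27. GCAT stood at -2.18 without sham replicate 2 but at -0.67 without sham replicate 1. Only CD82 and IFI27 fell by less than 1.5 times whichever array of that experiment was left out. Without sham replicate 2, TAOK2 (1.81), GCAT and IGKC (2.39) were called, with sham replicate 1 as the only control. They are named here after their values were seen. The exposed signals of TAOK2 (182 and 177) lay between its sham signals (40 and 572). Those of IGKC (317 and 279) did so too (44 and 533 in sham). Far more probe sets were called without the other sham array, when sham replicate 2 was the only control.

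CD82 and IFI27 were also the only tested probe sets at 2.0 W/kg whose signals differed at least 2-fold between each exposed and each sham array. The mean signal of CD82 was 81.9 ± 23.6 (SD, n = 2) in sham and 240.3 ± 35.1 (SD, n = 2) in exposed cells, and that of IFI27 was 530.1 ± 60.4 (SD, n = 2) and 207.4 ± 16.7 (SD, n = 2). The count of 2 was no larger than the count of 2 given by each of the other 2 ways of pairing the same 4 arrays.

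Among the 24 gene lists, 6 stood higher after exposure at 2.0 W/kg than the other genes by limma's camera test with a preset correlation of 0.01, and each call was lost with an estimated correlation (adjusted p = 0.675 with an estimated correlation for all 6). The estimated correlation called 0 lists in each of the 5 contrasts, and its power was not simulated. A call lost with it, here and below, therefore does not show that a list was unchanged. The fry test, which asks instead whether the genes of a list shifted in a common direction without reference to other genes, called 0 lists (adjusted p = 0.708 for these 6). All 49 tested ribosomal protein genes were positive, from RPL19 (0.13) to RPL36 (0.36), with a median of 0.25 (adjusted p = 1.35e-18). The mitochondrial respiratory chain list had 53 of 60 genes positive, a median of 0.19 (adjusted p = 4.62e-08) and values from -0.22 for NDUFS4 to 0.49 for NDUFB7, both subunits of complex I. Hypoxia and glycolysis genes had a median of 0.17, with 19 of 26 positive (adjusted p = 0.00266), the collagen prolyl hydroxylase P4HA2 highest (0.52) and the oxygen sensor EGLN1 lowest (-0.34). Oxidative stress genes had a median of 0.13, with 20 of 26 positive (adjusted p = 0.00725), between HMOX1, the inducible haem oxygenase (0.96), and the cystine transporter SLC7A11 (-0.48). Heat shock and protein folding genes had a median of 0.14, with 20 of 24 positive (adjusted p = 0.00735), between the collagen chaperone SERPINH1 (0.46) and HSPA4 (-0.28). Cytoskeleton genes had a median of 0.16, with 25 of 33 positive (adjusted p = 0.0112), between the tubulins TUBB4B (0.40) and TUBA4A (-0.60).

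No single member of these 6 lists passed, either over all genes or adjusted over the list alone. The array that stood apart moved with all 6 lists. Without it only the ribosomal proteins were called by the preset correlation (median 0.11, adjusted p = 1.84e-04), a call lost with an estimated correlation (adjusted p = 0.826 with an estimated correlation), and the medians of the other 5 lay between -0.03 and 0.03, with oxidative stress and the mitochondrial chain below 0. After quantile normalization 0 of the 24 lists were called, the ribosomal protein median was 0.01 and the heat shock and cytoskeleton medians turned to -0.03 and -0.02. A like shift ran through all genes by signal: the median difference was -0.14 in the 2284 most weakly expressed genes, -0.03 in the 2283 of the middle and 0.10 in the 2283 most strongly expressed.

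The remaining 18 lists did not pass at 2.0 W/kg, at adjusted p values of 0.0651 and above. Endoplasmic reticulum stress genes had a median of 0.11 (ATF6 0.66 to PPP1R15A -0.43), amino acid response and tRNA charging genes 0.11 (VEGFA 0.43 to PSAT1 -0.59) and cell cycle genes 0.07 (CCNB2 0.52 to CDC25C -0.30). Lists tied to genotoxic stress were close to 0, with medians of 0.07 for p53 targets (BAX 0.75 to GADD45A -0.69), 0.03 for DNA repair (BRCA1 0.56 to XRCC2 -0.97) and 0.01 for apoptosis regulators (BAX 0.75 to CASP2 -0.42). Immediate early genes had a median of -0.13, between DUSP2 (0.49) and NR4A1 (-1.17). Oestrogen receptor targets had a median of 0.06 (KRT19 0.29 to SERPINA1 -0.55), as did luminal epithelial markers (0.06, KRT19 0.29 to TJP3 -0.51). Interferon-stimulated genes had a median of -0.09, with 11 of 17 negative and HLA-B (0.18) highest. IFI27 was lowest, and it was the only member of any list at 2.0 W/kg that passed when adjusted over the list alone (adjusted p = 0.0257), but not over all genes.

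Medians of the smaller or less expressed lists at 2.0 W/kg were -0.11 for metallothioneins and metal response (SLC30A1 1.48 to MTF1 -0.73), -0.03 for cholesterol synthesis (NSDHL 0.79 to SREBF1 -0.44), 0.10 for NF-kB targets and cytokines (ICAM1 0.57 to NFKB2 -0.69), 0.12 for replication-dependent histones (H1-2 0.29 to H2AC8 -0.30), 0.07 for calcium handling (RCN2 0.25 to ORAI2 -0.43) and 0.01 for RNA decay and short-lived transcripts (TOB1 0.44 to PPP1R15A -0.43). Markers of cells that a pure MCF-7 culture should lack had medians of 0.01 for basal and mesenchymal cells (TWIST1 0.15 to COL6A1 -0.78) and -0.34 for blood and endothelial cells, of which only 3 were tested (ITGAM 0.11 to HBB -0.39). The mean over members took the other sign from the median for oestrogen receptor targets, DNA repair, RNA decay, metallothioneins, cholesterol synthesis, calcium handling and basal markers. Of these 18 medians, 12 took the other sign without sham replicate 2. Blood and endothelial markers came to 0.27, metallothioneins to 0.08, histones to -0.08, calcium handling to -0.07, p53 targets and cell cycle genes to -0.04. Endoplasmic reticulum stress, the amino acid response, DNA repair, apoptosis regulators, NF-kB targets and RNA decay came to just below 0. After quantile normalization 4 of them turned, luminal markers to -0.09, interferon-stimulated genes to 0.05, RNA decay to -0.02 and oestrogen receptor targets to -0.01.

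**Figure D2:**
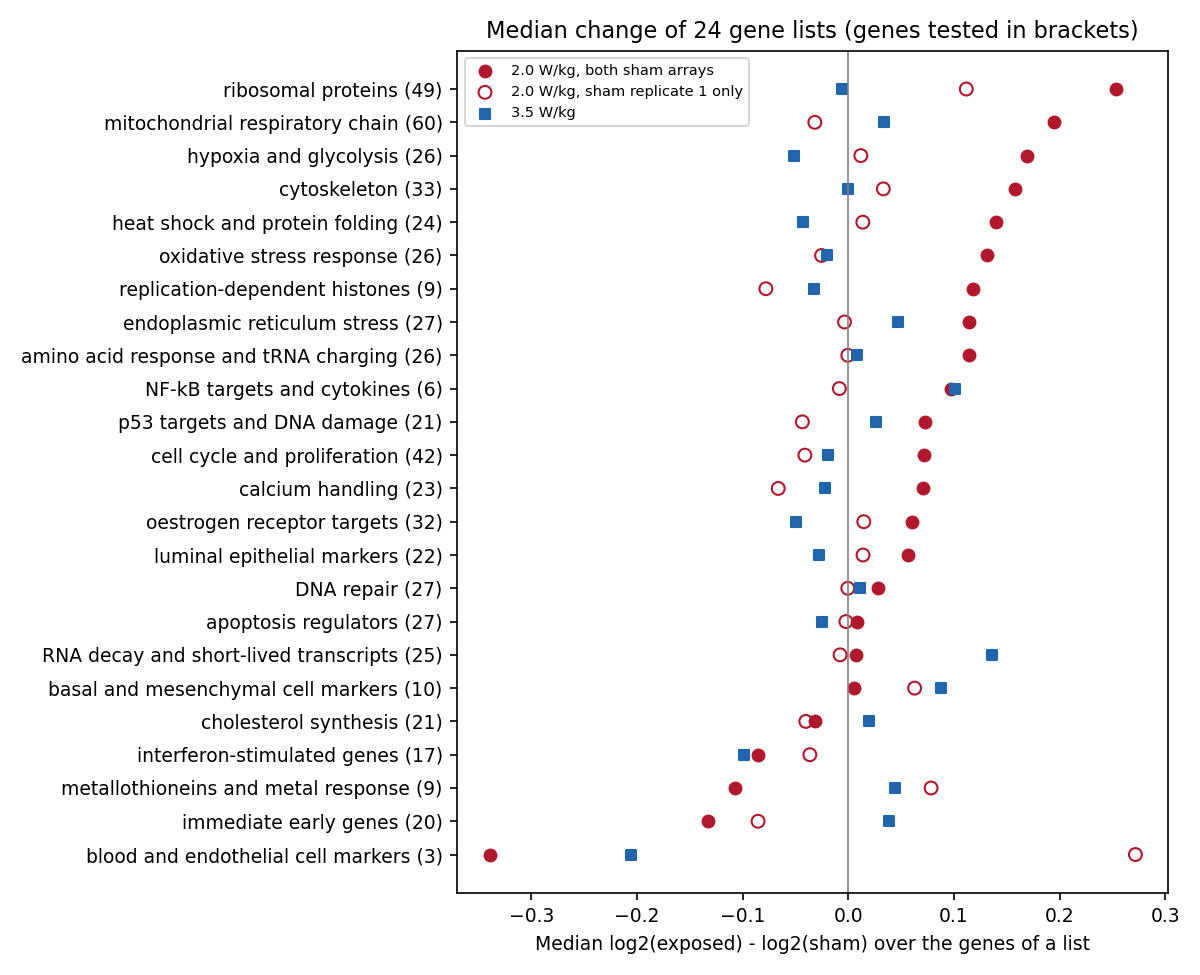
Median log2 difference, exposed minus sham, over the tested genes of each of the 24 gene lists, with the number of genes in brackets. Filled red circles show 2.0 W/kg with both sham arrays, open red circles 2.0 W/kg with sham replicate 1 as the only control, and blue squares 3.5 W/kg. The ribosomal protein list stands at 0.25 with both sham arrays, 0.11 with sham replicate 1 only and -0.01 at 3.5 W/kg.

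The second comparison asked the same question at 3.5 W/kg, with genes named by the same rule. PARG, the enzyme that degrades poly(ADP-ribose), had the highest difference at 1.07 ± 0.23 (SE), from a mean signal of 80.6 ± 26.9 (SD, n = 2) in sham to 183.7 ± 35.5 (SD, n = 2) in exposed cells. It was followed by RARS1, an arginyl-tRNA synthetase (0.78 ± 0.31), RBL2, a retinoblastoma family protein (0.76 ± 0.21), GTF2H3, a subunit of a general transcription factor (0.74 ± 0.24), and the lysosomal ATPase ATP13A2 (0.70 ± 0.29). ZC3H15 (0.70) and INTS7 (0.62) were also among the highest 10, as were the COPII coat protein SEC23B (0.67 ± 0.16), the translocon subunit SEC61B (0.64 ± 0.25) and DERL2, a factor of endoplasmic reticulum-associated degradation (0.64 ± 0.27). The lowest under that rule were NAP1L2, a nucleosome assembly protein (-1.19 ± 0.36), AXIN1, a negative regulator of Wnt signalling (-0.98 ± 0.36), TTI1 (-0.97 ± 0.29), MPPE1 (-0.88 ± 0.39) and the co-chaperone DNAJA4 (-0.85 ± 0.33). RPS6KB1, the ribosomal S6 kinase, stood at -0.81 ± 0.18 and SLC52A2, a riboflavin transporter, at -0.76 ± 0.17, ahead of PPP4R3A (-0.75), ADCK2 (-0.71) and CBFA2T2 (-0.66). Another probe set was tested for 7 of these 20 genes, and in none did it reach 50% of the named difference. The strongest other one stood at 0.02 for RPS6KB1 and SEC23B, 0.05 for ZC3H15 and -0.10 for SLC52A2, while PARG had no other. Without the rule, a probe set of CLTA whose arrays overlapped stood lower (-1.27 ± 0.71, SE). Leaving out 1 array of this experiment lowered 10 of the 20 values by over 1.5 times. RARS1 fell to 0.37, GTF2H3 to 0.39, DERL2 to 0.22, TTI1 to -0.48, DNAJA4 to -0.34 and PPP4R3A to -0.33 without exposed replicate 1. AXIN1 fell to -0.28, MPPE1 to -0.31 and CBFA2T2 to -0.41 without exposed replicate 2, and SEC61B to 0.25 without sham replicate 1.

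These 20 differences did not pass either. With limma, 0 of 11108 probe sets reached an adjusted p under 0.05 at 3.5 W/kg, every adjusted p was 1 after rounding, and 141 (1.27%) had an unadjusted p under 0.05. Both exposed arrays lay above both sham arrays for 1249 probe sets and below them for 1982, together 29.1% against 33.3% expected by chance. No tested probe set differed at least 2-fold in signal + 16 between each exposed and each sham array, and the other 2 ways of pairing the 4 arrays gave 0 as well. The 95% interval excluded a 2-fold change in signal + 16 for 10006 probe sets (90.1%), a share not directly comparable with that at 2.0 W/kg. Low signals at 3.5 W/kg were understated more than at 2.0 W/kg, since the same 16 units were added to values on a lower scale. NAP1L2 stood at -1.63 with a pseudocount of 1 and at -0.65 with 64, and ATP13A2 at 0.96 and 0.38. SEC23B, with more signal, still stood at 0.59 with a pseudocount of 64.

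**Figure D3:**
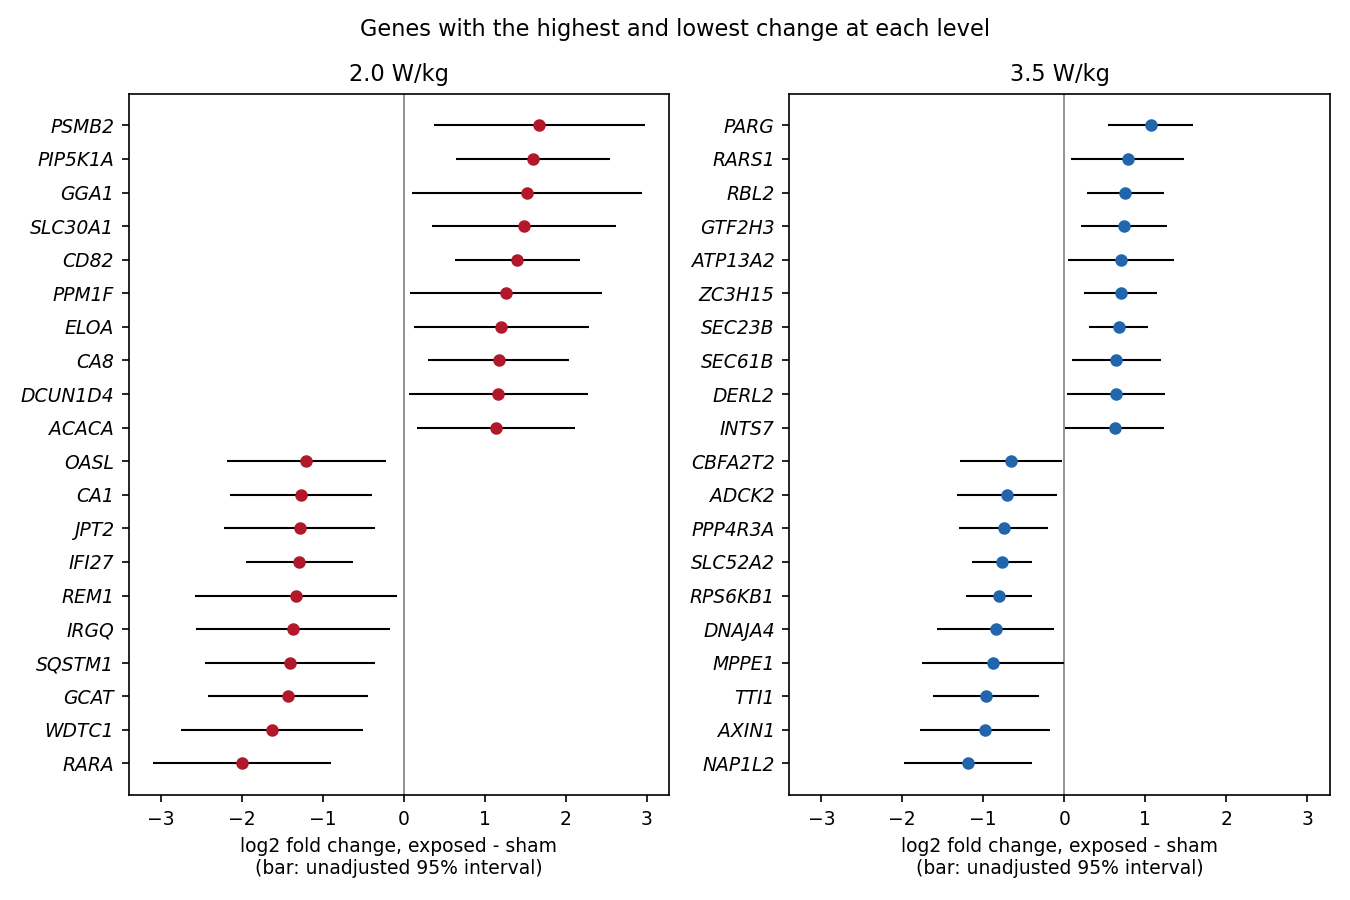
Log2 difference, exposed minus sham, for the 10 highest and 10 lowest genes at 2.0 W/kg (left) and 3.5 W/kg (right) among probe sets with a single symbol, no overlap between exposed and sham arrays and an unadjusted p under 0.05. Points are the estimates from 2 exposed and 2 sham arrays and bars their unadjusted 95% intervals. The values run from -1.997 (RARA) to 1.67 (PSMB2) on the left and from -1.19 (NAP1L2) to 1.07 (PARG) on the right, and none passed the test over all genes.

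At 3.5 W/kg 0 of the 24 lists passed camera with either correlation, fry called 0 as well, and no member passed when adjusted over the list alone. The list closest to the threshold was RNA decay and short-lived transcripts, with 17 of 25 genes positive and a median of 0.14 (adjusted p = 0.170), between the early-response repressor KLF10 (0.35) and HES1 (-0.51). Ribosomal proteins had a median of -0.01 (RPL34 0.36 to RPS14 -0.15), with 23 of 49 positive, and the mitochondrial chain a median of 0.03 (UQCRQ 0.34 to NDUFA5 -0.35). The stress lists were close to 0: heat shock and protein folding -0.04 (DNAJB6 0.34 to HSPA4 -0.30), oxidative stress -0.02 (KEAP1 0.32 to SLC7A11 -0.55), endoplasmic reticulum stress 0.05 (SEC61B 0.64 to CALR -0.39), p53 targets 0.03 (BAX 0.20 to FAS -0.30), DNA repair 0.01 (XRCC4 0.18 to OGG1 -0.35) and apoptosis regulators -0.02 (BAX 0.20 to TNFRSF1A -0.44). Immediate early genes had a median of 0.04, between SRF (0.30) and NR4A1 (-0.39). Oestrogen receptor targets had 24 of 32 genes negative and a median of -0.05 (MYBL1 0.27 to NRIP1 -0.38).

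Other medians at 3.5 W/kg were -0.02 for the cell cycle (CCNE1 0.22 to MCM6 -0.31), -0.05 for hypoxia and glycolysis (SLC2A1 0.23 to NDRG1 -0.42), 0.01 for the amino acid response (CEBPG 0.19 to SLC7A11 -0.55), 0.02 for cholesterol synthesis (INSIG1 0.31 to SCD -0.47), 0.04 for metallothioneins (MT1F 0.24 to MT1HL1 -0.21) and -0.10 for interferon-stimulated genes (IFITM2 0.17 to IRF1 -0.29). NF-kB targets had a median of 0.10 (NFKBIA 0.24 to NFKB1 -0.05), replication-dependent histones -0.03 (H1-2 0.18 to H2BC21 -0.11) and calcium handling -0.02 (ATP2B1 0.38 to PPP3CB -0.28). The cytoskeleton median was -5e-04 (TUBB2A 0.43 to EZR -0.45). Luminal markers stood at -0.03 (KRT19 0.19 to XBP1 -0.31), basal and mesenchymal markers at 0.09 (TWIST1 0.28 to COL6A1 -0.58) and the 3 blood and endothelial markers at -0.21 (HBB -0.07 to CD34 -0.47). The sign of the mean or of the test differed from that of the median for oxidative stress, p53 targets, the amino acid response, ribosomal proteins, histones, the cytoskeleton, calcium handling and basal markers.

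Genes chosen beforehand as markers of heat, growth, DNA damage and hormone response did not pass at either level. The heat shock genes HSPB1 and HSP90AA1 stood at 0.18 ± 0.19 (SE) and 0.19 ± 0.12 at 2.0 W/kg and at -0.06 ± 0.19 and 0.04 ± 0.12 at 3.5 W/kg, and after quantile normalization both 2.0 W/kg values turned to -0.05. JUN stood at -0.29 ± 0.26 and -0.05 ± 0.26, and MYC at 0.10 ± 0.23 and 0.13 ± 0.23. The p53 target CDKN1A stood at 0.01 ± 0.17 and 0.16 ± 0.17, while GADD45A, another damage-responsive gene, stood at -0.69 ± 0.23 at 2.0 W/kg (adjusted p = 0.891) and -0.12 ± 0.23 at 3.5 W/kg. HMOX1, which responds to oxidants, had a 95% interval of -0.03 to 1.95 at 2.0 W/kg and stood at -0.01 ± 0.44 at 3.5 W/kg. The oestrogen-induced genes TFF1 and PGR stood at 0.23 ± 0.13 and 0.23 ± 0.25 at 2.0 W/kg and at 0.09 ± 0.13 and 0.23 ± 0.25 at 3.5 W/kg, with TFF1 at 2.0 W/kg turning to -0.01 after quantile normalization, and BCL2 stood at 0.03 ± 0.16 and -0.08 ± 0.16. The reference genes ACTB and GAPDH stood at 0.24 ± 0.13 and 0.27 ± 0.16 at 2.0 W/kg, and at 0.01 and 0.02 after quantile normalization, and at -5e-04 ± 0.13 and -0.20 ± 0.16 at 3.5 W/kg. Without sham replicate 2, the 2.0 W/kg values of HSPB1 (-0.11), JUN (0.07), MYC (-0.29), CDKN1A (-0.04) and BCL2 (-0.0023) took the other sign, and HMOX1 fell to 0.19 ± 0.23 (SE), PGR to 0.04 ± 0.22 and GAPDH to 0.16 ± 0.16. GADD45A (-0.75), HSP90AA1 (0.16), TFF1 (0.18) and ACTB (0.195) stayed nearer to their values with both sham arrays. After quantile normalization CDKN1A turned to -0.06 at 2.0 W/kg, where PGR rose to 0.47, BCL2 rose to 0.12 and MYC fell to 0.03, and HMOX1 (0.07) and ACTB (0.05) turned at 3.5 W/kg. FOS was below the filter on weak signals, with mean signals of 13.9 and 2.11 in the 2 experiments, and HSPA1A, HSPA8 and TP53 had no probe set assigned to that gene alone.

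Averaged over both levels, 4 exposed against 4 sham arrays, and with each gene read by its probe set with the highest mean, the genes with the lowest unadjusted p were PARG (0.70 ± 0.16, SE), SLC52A2 (-0.49 ± 0.12), PAN2, a subunit of a deadenylase (-0.44 ± 0.11), NAP1L2 (-0.92 ± 0.25) and IFI27 (-0.75 ± 0.21). The first 4 lay on the same side in both experiments, with no overlap between exposed and sham arrays, whereas IFI27 overlapped at 3.5 W/kg. When any probe set could stand for a gene, a weaker one of SEC23B (0.59 ± 0.12, SE) had the lowest p of all and a weaker one of NUDT3 (-0.48 ± 0.12) was among the lowest 5, but their strongest probe sets stood at -0.04 and -0.18. None passed: limma called 0 probe sets (smallest adjusted p 0.976), with 260 (2.34%) at an unadjusted p under 0.05. Ribosomal proteins (median 0.13, adjusted p = 5.32e-13), the mitochondrial chain (0.11, adjusted p = 1.15e-06) and the cytoskeleton (0.08, adjusted p = 0.0331) were called by camera over both levels and lost with an estimated correlation (adjusted p = 0.777 with an estimated correlation for each). Without sham replicate 2 of 2.0 W/kg only the ribosomal proteins were called (median 0.06, adjusted p = 7.46e-04), a call lost with an estimated correlation (adjusted p = 0.87 with an estimated correlation). The other 2 were not called (adjusted p = 0.711 and 0.509). After quantile normalization 0 lists were called, with the cytoskeleton median at -0.02. Probe sets were called without the first sham replicate of 2.0 W/kg, when sham replicate 2, which stood apart, was the only control at that level.

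The levels were then compared directly. By the probe set with the highest mean, the genes with the lowest unadjusted p for a difference between levels were TET3, an enzyme of DNA demethylation (1.001 at 2.0 W/kg and -0.63 at 3.5 W/kg), CD82 (1.40 and -0.59), DDA1 (-0.78 and 0.20), FPGS, a folate-metabolising enzyme (0.43 and -0.53), and ATP13A2 (-0.70 and 0.70). With any probe set allowed, a weaker one of CLTA was among the lowest 5 (-0.82 ± 0.21, SE, between levels, against -0.11 for its strongest). None passed: limma called 0 probe sets (smallest adjusted p 1), with 166 (1.49%) at an unadjusted p under 0.05. Calls arose without the first sham replicate of 2.0 W/kg, when sham replicate 2 was the only control at that level. Across probe sets, which are not independent replicates, the differences at the 2 levels correlated at a Pearson r of 0.12 and a Spearman rho of 0.12. The 8 other combinations of ways to pair the arrays within levels gave a Pearson r between -0.17 and 0.12, and without sham replicate 2 of 2.0 W/kg the real combination gave -0.09.

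The sham groups, which received no field, give the background difference between the experiments. As deposited, 10987 probe sets were lower in the 3.5 W/kg sham group and 0 higher, with a median of -1.78 that equals a 3.44-fold difference in scale. On a common scale, each array set to the same 75th percentile, the median was 0.06 and limma called 0 probe sets, with 1169 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0695. By the probe set with the highest mean, the genes with the lowest p on that scale were the RNA helicase DDX21 (1.43 ± 0.19, SE), IFI27 (-2.12 ± 0.32), GTF2I (-0.97 ± 0.16), the nuclear import factor TNPO3 (0.91 ± 0.16) and PHGDH, an enzyme of serine synthesis (0.89 ± 0.16). With any probe set allowed, weaker ones of RHOBTB3 (1.37 ± 0.16, SE, the smallest adjusted p), LSM12 (1.42 ± 0.20) and KPNA6 (1.82 ± 0.28) were among the lowest 5, with 0.24, 0.53 and 0.31 for their strongest. By camera, 5 lists differed between the sham groups as deposited, 0 of them with an estimated correlation (lowest adjusted p = 0.663 with an estimated correlation), and 10 differed on the common scale. Relative to that common scale, ribosomal proteins (adjusted p = 4.01e-06), cell cycle genes (adjusted p = 2.19e-05) and the mitochondrial chain (adjusted p = 8.11e-05) were higher in the 3.5 W/kg sham group, as were 3 further lists. Immediate early genes, interferon-stimulated genes, basal markers and RNA decay were lower. All 10 calls were lost with an estimated correlation (lowest adjusted p = 0.573 with an estimated correlation). This contrast holds sham replicate 2 of 2.0 W/kg. Without it 7 lists were called by the preset correlation and 0 by the estimated one (lowest adjusted p = 0.393 with an estimated correlation). Of the 7, 5 were lower, histones most clearly (-0.36, adjusted p = 6.38e-04), and cell cycle genes (adjusted p = 0.0389) and the amino acid response were higher. The ribosomal proteins (adjusted p = 0.0511) and the mitochondrial chain (adjusted p = 0.792) were not called. After quantile normalization 2 lists were called, cell cycle genes higher (adjusted p = 0.00482) and RNA decay lower (adjusted p = 8.79e-04), both lost with an estimated correlation (lowest adjusted p = 0.241 with an estimated correlation). For the ribosomal proteins the direction of the test turned from lower to higher between the scales.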

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

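The tests of exposure as the cause of the list shifts, of the mitochondrial list against matched random lists, of the signal distribution and of RNA degradation were chosen after the result was seen, and the others before. The use of quantile normalization to judge the ribosomal and mitochondrial lists was likewise added after its result was seen, as was the weight given to the correlation of their members.

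For 5 gene lists the difference between exposed and sham cells itself differed between 3.5 and 2.0 W/kg by camera with the preset correlation: ribosomal proteins by a median of -0.28 (adjusted p = 1.31e-11), hypoxia and glycolysis by -0.20 (adjusted p = 4.72e-04), oxidative stress by -0.18 (adjusted p = 0.0309), the mitochondrial respiratory chain by -0.17 (adjusted p = 4.72e-04) and heat shock and protein folding by -0.15 (adjusted p = 0.0257). Each was lost with an estimated correlation (adjusted p = 0.73 with an estimated correlation). Of the genes behind them, 47 of 49 ribosomal protein genes and 23 of 26 hypoxia genes had a lower difference at 3.5 W/kg. Without sham replicate 2 of 2.0 W/kg 0 of the 24 lists differed between levels, and the ribosomal proteins came closest (adjusted p = 0.071).

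The shift of 6 lists at 2.0 W/kg underlies these differences. For the 5 lists other than ribosomal proteins the shift depended on sham replicate 2. The mean of their medians was 0.16 against both sham arrays and 3e-04 against sham replicate 1 alone. These lists were called with sham replicate 2 included, and a single control array remained without it. The fall therefore cannot decide whether exposure had an effect on them. A candidate explanation is the narrower signal range of sham replicate 2, which would raise every strongly expressed gene in the exposed group: among 10000 random lists matched for expression, only 1 of the 5 lists lay above the central range. That list was the mitochondrial chain, whose median exceeded 99.41% of matched lists, and the ribosomal proteins exceeded 99.65% of theirs (median 0.25 against 0.22 for the matched lists). Random matching was an incomplete bound for the ribosomal proteins, which ranked at 99.4% of the expression range. That reason does not hold for the mitochondrial chain, at 93.4%. For both, however, the random lists drew genes independently, whereas the members were correlated (estimates of 0.555 and 0.417, or 0.201 and 0.0533 without sham replicate 2), so the matched range may have been too narrow. The mitochondrial chain also exceeded 98.42% of matched lists at 3.5 W/kg, where that array played no part. Equalising the distributions by quantile normalization left medians of 0.01 (camera, adjusted p = 0.808) and 0.06 (camera, adjusted p = 0.613). For the ribosomal proteins this step cannot decide, because it sets the strongest signals of every array to the same values. A shared shift of genes at the top of the range is then largely removed, whatever its cause. For these 2 lists the signal range stays open. Against sham replicate 1 alone the ribosomal median was 0.11, less than with both arrays, and with that array as the only control an effect of exposure on ribosomal protein transcripts cannot be told apart from the spread of sham arrays.

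Sham replicate 2 of 2.0 W/kg itself was the second pattern. The shape of its signal distribution alone does not account for its place: after quantile normalization its highest correlation with another array was 0.9334, below the lowest value among the other 7 (0.9725). RNA degradation, which raises the 3-prime over the 5-prime signal, is argued against by a GAPDH log2 difference of -0.3369, below the range of the other arrays (-0.2844 to -0.0342). A different RNA composition, whether from the culture or another sample, stays open, because probe sets of the same gene deviated together on this array only weakly (r = 0.1192 over 2142 genes). The other sham array gave 0.119, but its deviation was taken from a mean that held this array, so it is no independent yardstick. The 3.5 W/kg arrays, where this array played no part, gave 0.0301 to 0.0875. The SD of the deviations was 0.5689 on this array and 0.2106 to 0.2407 on the 3.5 W/kg arrays. Most of the wider deviation on this array was thus not shared between probe sets of a gene. No biological explanation beyond the sham label was available to test.

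The third pattern was the count of called probe sets over both levels. It was 0 in the real split of the 8 arrays into 4 and 4, so all 35 splits gave as many by construction and this count says nothing about chance. The highest other count was 11090, in the split that follows the 2 experiments and so reads their difference in scale, and apart from that split every other gave 0. In fits with a term for level, used for every split but the one by experiment, the real split had 310 probe sets at an unadjusted p under 0.05, a number that 19 of the 35 splits reached, itself included.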

How the results depend on the processing

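Array weights and the common scale combined with leaving out sham replicate 2 of 2.0 W/kg were chosen after the data had been seen. The count of called probe sets was 0 in all 4 exposure contrasts under both pseudocounts, both filters, both normalizations, eBayes without a trend, array weights, the replicate block and, for the single levels, only the 4 arrays of the level, where 115 and 359 probe sets had an unadjusted p under 0.05 at 2.0 and 3.5 W/kg. Leaving out single arrays moved it to between 0 and 2154 at 2.0 W/kg, 0 and 1198 over both levels and 0 and 599 between levels, the highest each time without sham replicate 1 of 2.0 W/kg, and the cause was not tested. At 3.5 W/kg it stayed at 0. Array weights gave 0.3038 to both 2.0 W/kg sham arrays, since with 2 arrays in a group both deviate equally from their mean.

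The 2-fold count over all pairs at 2.0 W/kg (2) was 18 at 1.5-fold, 8 with the replicate block (same-numbered pairs, fewer pairs to pass), 0 with a pseudocount of 64, 80 with all probe sets, 0 in the upper 25%, 13 on the common scale without sham replicate 2, and 14 to 625 when an array was left out. At 3.5 W/kg (0) it was 6 at 1.5-fold, 1 with the replicate block, 1 with a pseudocount of 1, 1 with all probe sets, and 3 to 12 without an array of that level. A lower fold, or more probe sets, cannot lower the count. The highest count at 2.0 W/kg came without sham replicate 1, when sham replicate 2, which stood apart, was the only sham array of that level.

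The 6 lists called at 2.0 W/kg became 0 with an estimated correlation, 0 with fry (another question), 0 after quantile normalization, 1 on the common scale without sham replicate 2, and 1 to 8 without an array. At 3.5 W/kg (0) it was 1 with all probe sets and 0 to 2 without an array. Between the sham groups (5) it was 0 with an estimated correlation, 24 with fry (which reads the scale), 1 with the mean over a gene's probe sets, 20 with all probe sets, 2 after quantile normalization, 10 on the common scale, and 2 to 15 without an array. The sham groups differed in 17563 probe sets with all tested, 5551 in the upper 25%, 0 after quantile normalization, 0 on the common scale and 6 on that scale without sham replicate 2. The correlation between levels (0.1156) was -0.1004 on the common scale without that array and -0.0931 to 0.1612 when single arrays were left out. Where no construction explains a move, the cause was not tested.

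Of 2787 alternative values of named genes, 2644 stayed on their side, 85 changed sign without passing in either fit, 58 passed only in the alternative (57 of them without sham replicate 1 of 2.0 W/kg) and 0 reversed after a call. No named gene of the highest and lowest 10 changed sign. The rule of no overlap fixed this in advance for the pseudocounts and for single arrays left out. Array weights, the replicate block and eBayes without a trend leave a difference as it is and change only its test. Part of the 2644 was therefore fixed by construction. Replicate numbers pair no arrays by label, and deviations of same-numbered arrays correlated at 0.139 (2.0 W/kg) and 0.0514 (3.5 W/kg). The replicate block called 0 probe sets in each exposure contrast and 6 and 0 lists at 2.0 and 3.5 W/kg. Weak signals limit the data: probe sets near the added 16 units, more of them on the lower 3.5 W/kg scale, have differences pulled towards 0.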

Other observations

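The comparison of the experiments on a common 75th percentile, and the genes named from it, were chosen after the data had been seen. Irrespective of field, several transcripts stood apart between the experiments. Without sham replicate 2 of 2.0 W/kg, limma called 213 probe sets higher and 172 lower in the 3.5 W/kg experiment (1927 at an unadjusted p under 0.05), and with all 8 arrays 54 and 26, all 80 of them among the former. After quantile normalization 367 were called without that array, 350 of them shared with the common scale. Higher at 3.5 W/kg in both fits were CTNNB1, the beta-catenin of adhesion and Wnt signalling (1.34 ± 0.22, SE), the RNA helicase DDX21 (1.29 ± 0.11), the interferon-inducible IFI44 (1.10 ± 0.16), the translation factor EIF5B (1.04 ± 0.15), the actin crosslinker ACTN4 (1.02 ± 0.16) and PHGDH (0.68 ± 0.11). Lower in both fits were IFI27 (-1.64 ± 0.22), the actin-severing gelsolin GSN (-0.98 ± 0.15) and the initiator caspase CASP8 (-0.80 ± 0.15). These genes kept their sign after quantile normalization. The experiments were scaled separately, and the labels do not give what else differed between them. Sham cells received no field, yet their common-scale log2 means at 2.0 and 3.5 W/kg were 8.57 and 10.02 for CTNNB1. They were 8.91 and 10.33 for DDX21, 7.23 and 8.16 for IFI44, and 8.42 and 9.35 for EIF5B. ACTN4 stood at 9.05 and 9.98, IFI27 at 8.12 and 6.0, and GSN at 8.73 and 7.85. For these genes the values argue against the field level as the source. The sham groups can be read in the same way for other called genes, and they did not all behave alike. In sham cells TNPO3 stood at 8.26 and 9.17 and VTCN1 at 7.4 and 6.37. BAX stood at 6.98 and 6.94 and LYPD3 at 6.59 and 6.39. All these sham means hold sham replicate 2 of 2.0 W/kg, and the remaining called genes were not read this way.

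By camera on the same scale without that array, replication-dependent histones were lower at 3.5 W/kg (median -0.19, adjusted p = 5.37e-04), with interferon-stimulated genes (-0.11, adjusted p = 0.0344), RNA decay and short-lived transcripts (-0.12, adjusted p = 0.0328) and endoplasmic reticulum stress genes (-0.07, adjusted p = 0.0425). Cell cycle genes (0.16, adjusted p = 0.00127), amino acid response and tRNA charging genes (0.18, adjusted p = 0.00325) and heat shock genes (0.19, adjusted p = 0.039) were higher, and all 7 calls were lost with an estimated correlation (adjusted p = 0.365 with an estimated correlation). After quantile normalization the heat shock call was lost (adjusted p = 0.086) and the directions were the same. Among the interferon-stimulated genes the called members went both ways, with IFI44 higher and IFI27 and HLA-B (-0.50 ± 0.11) lower.

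IFI27 held the lowest difference of its list at 2.0 W/kg and was among the genes furthest apart between experiments. On the common log2 scale it stood at 8.12 in 2.0 W/kg sham, 6.96 in 2.0 W/kg exposed, 6.0 in 3.5 W/kg sham and 5.75 in 3.5 W/kg exposed cells, so the sham groups differed more than exposed and sham cells did at either level.

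A further check set pairs of probe sets of the same gene against each other over 2142 genes. After quantile normalization, without sham replicate 2 of 2.0 W/kg, the difference between experiments correlated between such probe sets at r = 0.296 (7 arrays), and exposed minus sham at 0.0805 at 2.0 W/kg (3 arrays) and 0.0661 at 3.5 W/kg (4 arrays), across genes that are not independent replicates. With that array the first 2 values were 0.2659 and 0.0922. The values rest on different numbers of arrays.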
